A study of Mus musculus with 18 samples.

How the data were processed

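Gene expression was measured on 18 Agilent arrays with 2 dyes, each with 1 sample of bone marrow derived mouse macrophages (Cy5) set against an untreated macrophage reference (Cy3). Per the labels the marrow came from mice of 8 to 10 weeks, the cells were grown in 10 ng/ml M-CSF for 7 days, and the labelling used 500 ng of total RNA. The design text speaks of a common reference, with 3 to 5 independent biological replicates per condition. Per the sample labels the albumin arrays had 4 h of albumin, the LPS arrays 4 h of LPS, and the heme arrays 4 h of 200 µM heme-albumin followed by 4 h of LPS. The treatment protocol speaks of heme-albumin or albumin alone before LPS at 10 ng/ml, while the labels of the LPS arrays name no albumin, so whether these cells had albumin first is not given in the sources used here.

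The deposited values are log10 ratios of the sample channel over the reference channel, which per the submitters' processing notes came from Agilent Feature Extraction 10.5.1.1. The scale is not stated in the labels. It was inferred from the form and range of the values, which are those that this program writes for its log10 ratio. Background and dye correction and the genotype of the reference RNA are not given in the sources used here. Of 44397 features 33026 carried a gene symbol and 11371 carried none; 1500 features and 486 genes were listed at exactly 0 on every array, and no value was missing. Symbols were checked by gene identifier against a reference table of gene names, which matched 32438 probes and changed 0 symbols. The files used here give no positions of the probes.

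The log10 values were put on the log2 scale and averaged over the probes of a gene, which gave 22485 genes, 16347 of them with 1 probe. Features needed a value in at least 2 arrays of every group, which removed none. Among 94 named genes with several probes 20 had probes whose heme effect in wild type differed by more than 1 log2 unit, Maf by 2.88, the largest of these. Group means were fitted in 1 model over all 18 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 1 spread per gene for all groups. The p values were adjusted over all genes (Benjamini-Hochberg). A gene was called at an adjusted p under 0.05, the tests of genes being two-sided. The 7 comparisons were LPS against albumin, heme and LPS against LPS, and heme and LPS against albumin in wild type; heme and LPS against LPS in the knockout; the interaction, which is the heme effect in the knockout minus that in wild type; and knockout against wild type under LPS and under heme and LPS. Simulated data with 4-fold changes were called in 70% to 93% of cases and 2-fold changes in 33% to 57%, depending on the comparison, with 3.55% to 8.82% false calls. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

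The 29 gene lists were NRF2 targets; heme and iron handling; pro-inflammatory cytokines and enzymes; chemokines; type I interferon response; NF-kB pathway and its feedback; LPS receptor and signalling; MHC class II presentation; MHC class I presentation; co-stimulation; anti-inflammatory and alternative activation; scavenger receptors and efferocytosis; integrated stress response; heat shock and protein folding; cholesterol synthesis; LXR targets and lipid handling; lysosome; glycolysis and hypoxia response; oxidative phosphorylation; cell cycle; p53 targets and cell death; macrophage identity; and markers of neutrophils, B cells, T and NK cells, erythroid cells, dendritic cells, mast cells and basophils, and stromal cells. Each list was tested against all other genes with limma's camera at its preset correlation of 0.01, adjusted over the 203 tests of 29 lists in 7 comparisons, of which 78 passed. With an estimated correlation 7 of the 78 passed: NRF2 targets in 5 comparisons, the cytokine list under LPS against albumin, and glycolysis and hypoxia response in knockout against wild type under heme and LPS. Median, mean and test had the same sign in each of the 78. Counts adjusted over the list alone used the members of the list only. Symbols not measured were looked up through synonyms, which put Pigq in place of Gpi1 and Eno1b in place of Eno1 in the glycolysis list, although these are other genes.

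Named genes followed a rule. It took 19 genes named in advance; per comparison the 8 called genes with the largest rise and the 8 with the largest fall whose arrays did not overlap between groups, with no rule on overlap for the interaction; and per comparison and list up to 4 called members and up to 2 members not called, by size of change. Genes of the interaction could be given in both genotypes. Genes that LPS raised at least 4-fold in wild type were followed under heme, beside 20 simulations of unchanged groups. In these all arrays were drawn anew and independently. The drawn wild-type LPS arrays served both to pick the genes and in the comparison with heme. The groups, comparisons, tests, lists, the named-gene rule and most alternatives were fixed before the data were examined.

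Arrays of a group carry letters, and it was checked whether arrays of the same letter deviated together from their group means. They did in each letter for LPS and heme in the knockout (correlation 0.216 to 0.586 over 4 letters), for wild type and knockout under LPS (0.196 to 0.579 over 3) and for wild type and knockout under heme (0.228 to 0.533 over 3). For the wild-type heme comparison it was 0.476 in letter a, but 0.0121 in b and 0.0143 in c. For albumin against LPS-treated groups the values lay between -0.0226 and 0.0152. Whether a letter stands for a day or a batch of cells is not given in the sources used here, and the letter was used as a block in an alternative fit.

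Alternatives tried were centring each array on its median, which was already 0 on all 18 arrays, quantile normalization, robust eBayes, array weights, the most variable probe per gene, each probe on its own, only the genes with variance above the median, leaving out probes at exactly 0 on most arrays, the replicate letter as a block, only the arrays of the groups compared, a 2-fold minimum, other minimum folds for LPS-induced genes, and leaving out each array. Chosen after seeing the data were leaving out the 4 LPS-treated arrays lettered a, taking exact 0 as missing, centring on the nonzero median, the letter as a block for the LPS-induced genes, leaving out each array for named genes and for the correlation of the heme effects, and leaving Pigq and Eno1b out of the glycolysis list. No array was left out of the reported fit, and the 11371 features without a symbol were used only for counts.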

Results

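Gene expression was measured in bone marrow derived macrophages of mice, grown from marrow with M-CSF, the growth factor that drives macrophage differentiation. The cells were wild type (Nrf2+/+) or lacked Nrf2 (Nrf2-/-), the transcription factor NRF2 that switches on antioxidant and detoxification genes and is encoded by Nfe2l2. LPS is the endotoxin of Gram-negative bacteria, and heme, the iron-bearing group of hemoglobin, was given as a complex with albumin. Each of the 18 arrays set 1 sample against an untreated macrophage reference, with 3 wild-type samples under albumin alone, 3 wild-type samples under LPS, 3 wild-type samples under heme followed by LPS, 4 knockout samples under LPS and 5 knockout samples under heme followed by LPS. Heme-albumin was given at 200 µM for 4 h and LPS at 10 ng/ml for 4 h. The knockout has no group without LPS. Values are log2 ratios to the reference, and changes are differences of group means of these ratios with the standard error (SE) of the limma fit over all arrays. The number of arrays limits the precision. Between 17.9% and 48.8% of the features of an array were listed at exactly 0, and the LPS-treated arrays lettered a stood at 44.4% to 48.8%. Within a group the arrays correlated at 0.55 to 0.58 under albumin, 0.79 to 0.87 in wild type under LPS, 0.64 to 0.80 in wild type under heme and LPS, 0.83 to 0.89 in the knockout under LPS and 0.67 to 0.86 in the knockout under heme and LPS.

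Nfe2l2, the gene knocked out, was listed at exactly 0 on all 9 knockout arrays. In wild type its log2 ratio was -0.07 ± 0.12 (SD, n = 3) under albumin, -0.29 ± 0.40 (n = 3) under LPS and 0.64 ± 0.46 (n = 3) under heme and LPS, and 2 of the 9 wild-type arrays, both under albumin, were also at exactly 0. The ratio is relative to the reference, whose genotype is not given, so a 0 does not show by itself that the transcript was absent. The position of the probe relative to the deleted part is not given either. In wild type Nfe2l2 rose with heme by 0.94 ± 0.19 (SE, limma adjusted p = 0.00394), and in the knockout the difference was 0.00 ± 0.16. Nqo1, a quinone reductase that NRF2 controls, stood at 3.18 ± 0.34 (SD, n = 3) in wild type under heme and LPS and at 0.46 ± 0.47 (SD, n = 5) in the knockout.

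The comparison of LPS with albumin in wild type asked what the endotoxin did to these cells without heme. By the labels the albumin arrays had 4 h of albumin and the LPS arrays 4 h of LPS, with no albumin named. The albumin, or the time in culture if albumin came first, can therefore differ as well. LPS raised genes of inflammation. Il12b, a subunit of interleukin-12 and interleukin-23, rose by 8.37 ± 0.85 and Ptgs2, the inducible prostaglandin synthase, by 9.10 ± 0.52. Il1b, whose product the inflammasome activates, rose by 7.27 ± 0.27, the tumor necrosis factor gene Tnf by 4.74 ± 0.21, and Nos2, the inducible nitric oxide synthase, by 4.94 ± 0.41 (SE, n = 3 per group). Il6, which encodes a fever-inducing cytokine, stood at 10.96 ± 0.62 (SD) under LPS and was listed at exactly 0 on all 3 albumin arrays, so that the size of its rise is uncertain. The activation antigen gene Cd69 rose by 9.13 ± 0.68, Cxcl10, which encodes an interferon-induced chemokine, by 9.48 ± 1.24, and the anti-inflammatory cytokine gene Il10 by 5.02 ± 0.36. Among the genes that fell were Lyl1, a hematopoietic transcription factor gene, with -5.41 ± 0.31, Bmf, which promotes apoptosis, with -5.90 ± 0.54, Fam214a with -6.46 ± 0.43 and Gpr183, an oxysterol receptor gene, with -4.61 ± 0.50. For each of these genes no array of either group overlapped with the other group.

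By list, 15 of the 23 measured pro-inflammatory cytokines and enzymes rose and 0 fell, 16 when adjusted over the list alone, and this call held with an estimated correlation (adjusted p = 0.0385). Csf2 (3.60 ± 1.97, limma adjusted p = 0.205) and Csf3 (3.13 ± 1.83, adjusted p = 0.235) were not past the threshold. Without LPS array a Csf3 stood at 4.75 and was still not past it (limma adjusted p = 0.0853). Of the 18 chemokines 15 rose, 16 when adjusted over the list alone, among them Cxcl2 by 7.36 ± 0.57, Cxcl1 by 6.20 ± 0.53 and Ccl4 by 5.65 ± 0.44; the list had an adjusted p = 0.0833 with an estimated correlation. In the type I interferon response, the antiviral program downstream of interferon beta, 34 of 36 genes rose and 34 did when adjusted over the list alone, with a median of 3.72 (adjusted p = 0.388 with an estimated correlation). Gbp5, a guanylate-binding protein gene, rose by 8.59 ± 0.72, Ifnb1, interferon beta itself, by 7.05 ± 0.74 and Ifit1 by 7.06 ± 0.95. The NF-kB pathway and its feedback genes had 26 of 27 members up, 26 when adjusted over the list alone (adjusted p = 0.0986 with an estimated correlation), including Nfkbiz with 6.05 ± 0.43 and the inhibitor gene Tnfaip3 with 5.64 ± 0.76. All 17 genes of MHC class I presentation rose, 17 when adjusted over the list alone, with a median of 1.54 (adjusted p = 0.271 with an estimated correlation). Among 12 co-stimulation genes 7 rose, 9 when adjusted over the list alone (adjusted p = 0.172 with an estimated correlation), among them Cd40 by 4.13 ± 0.44 and Cd274, which encodes PD-L1, by 3.36 ± 0.39. In MHC class II presentation 3 of 13 genes rose and 1 fell, and the list was not past the threshold (adjusted p = 0.182).

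NRF2 targets were not past the threshold as a list under LPS alone. This list holds Nfe2l2 itself, the gene knocked out. Of 35 members 9 rose and 5 fell, with a median of -0.03, a mean of 0.08 and a test pointing up (adjusted p = 0.797). For Hmox1, which encodes the heme-degrading enzyme heme oxygenase, the difference was 0.12 ± 0.34 (adjusted p = 0.888), which is not past the threshold. Of 29 heme and iron handling genes 4 rose and 8 fell (adjusted p = 0.493), with Lcn2, a siderophore-binding protein gene, up by 2.85 ± 0.26. In the cell cycle list 7 of 31 genes fell and 1 rose, with a median of -0.91 (adjusted p = 0.745 with an estimated correlation), among them Cdt1 (-2.76 ± 0.47) and Aurka (-1.94 ± 0.38), both needed for cell division; with the replicate letter as a block 13 fell. Of markers of other cells limma called 1 neutrophil gene higher and 1 lower, 2 B cell genes lower, 2 T and NK cell genes higher, 1 erythroid gene higher, 1 dendritic cell gene higher and 1 lower, 1 mast cell gene lower and 2 stromal genes higher. Among them were the neutrophil gene Ngp (1.75 ± 0.35) and the NK cell gene Ncr1 (1.42 ± 0.33). With Nkg7 (0.34 ± 0.08) and Itgae (-1.32 ± 0.33) these alone kept their calls whichever 1 array was left out. Over all 22485 genes limma called 2768 higher and 3665 lower under LPS than under albumin. The labels give 4 h of treatment for both groups, of albumin on the albumin arrays and of LPS on the LPS arrays. Arrays of 1 letter did not deviate together between albumin and the LPS-treated groups.

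Heme before LPS was compared with LPS alone in wild type to see how heme changed the response of the cells. By the labels the heme arrays had 4 h of heme-albumin and then 4 h of LPS, and the LPS arrays 4 h of LPS. In either genotype the time in culture and the albumin can differ as well. Hmox1 rose by 4.91 ± 0.34, and Gclc and Gclm, the subunits of the enzyme that starts glutathione synthesis, by 5.32 ± 0.48 and 4.14 ± 0.40. Srxn1, a sulfiredoxin gene, rose by 4.51 ± 0.38, Nqo1 by 3.42 ± 0.32 and Txnrd1, a thioredoxin reductase gene, by 2.87 ± 0.34 (SE, n = 3 per group). Slc40a1, the iron exporter ferroportin, rose by 5.85 ± 0.84, and Spic, a transcription factor gene of iron-recycling macrophages, by 4.49 ± 0.61. Cxcl5, which encodes a neutrophil-attracting chemokine, rose by 7.71 ± 0.99, from 2.49 ± 2.33 (SD) under LPS to 10.20 ± 1.28 under heme and LPS. Among the genes that fell were Gbp4 (-7.33 ± 1.14) and Gbp11 (-6.66 ± 0.87), both of the guanylate-binding protein family, and Fgl2, a prothrombinase gene (-7.04 ± 0.54). Iigp1, an interferon-induced GTPase gene (-5.92 ± 1.02), Tnfsf10, which encodes the death ligand TRAIL (-6.35 ± 0.95), the chemokine gene Ccl12 (-5.82 ± 1.19) and the follistatin gene Fst (-5.66 ± 0.92) fell too. Probes of the guanylate-binding protein family, of Ccl2 and Ccl12, and of Ifit1 and its paralogs can share targets, so the single members are uncertain.

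Of the 35 NRF2 targets 30 rose and 0 fell, 31 and 1 when adjusted over the list alone. Nfe2l2 itself is 1 of the 30. The median was 1.99, and the call held with an estimated correlation (adjusted p = 0.000621). Slc7a11, the cystine transporter gene, rose by 5.54 ± 1.40 (limma adjusted p = 0.0139) and lost its call without the heme and LPS array c or the LPS array a, with an adjusted p of up to 0.0739, and without all LPS-treated arrays lettered a (adjusted p = 0.0607). Among 29 heme and iron handling genes 10 rose and 2 fell, 10 and 2 when adjusted over the list alone (adjusted p = 0.261 with an estimated correlation). The heme transporter gene Slc48a1 rose by 2.94 ± 0.19. Of these risers Hmox1, Blvrb, Fth1, Ftl1 and Slc48a1 are also among the NRF2 targets that rose. In the integrated stress response 5 of 27 genes rose, 5 when adjusted over the list alone, and in heat shock and protein folding 5 of 19, 8 when adjusted over the list alone; both lists had an adjusted p = 0.626 with an estimated correlation. Slc3a2, an amino acid transporter subunit gene, rose by 2.11 ± 0.33, and the chaperone gene Hsph1 by 2.90 ± 0.58. Without the LPS-treated arrays lettered a the integrated stress response had 3 genes up and was not past the threshold even with the preset correlation (adjusted p = 0.146).

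The type I interferon response fell in 34 of 36 genes, 35 when adjusted over the list alone, with a median of -2.65; the list had an adjusted p = 0.363 with an estimated correlation. Gbp3 (-4.38 ± 0.98) and Ifi47 (-4.33 ± 0.83) were among those that fell, and Isg15 (-2.04 ± 0.89, limma adjusted p = 0.178) and Oasl1 (-0.72 ± 0.44, adjusted p = 0.391) were not past the threshold. The 3 arrays differed in this list: its median log2 ratio was 1.93 on array a, -0.86 on array b and -0.13 on array c. Ifit1 (-3.39 ± 0.95, adjusted p = 0.0253) lost its call without array b or c of heme and LPS or without any 1 of the 3 LPS arrays, with an adjusted p of up to 0.122, and under quantile normalization (adjusted p = 0.117). Cxcl10 had a difference of -3.70 ± 1.24 (adjusted p = 0.0634) and was not past the threshold. Without heme and LPS array a Cxcl10 (-5.60, adjusted p = 0.000578) and Isg15 (-3.24, adjusted p = 0.00842) were past it. Isg15 went the other way without heme and LPS array b, to -1.19 (limma adjusted p = 0.572). MHC class I presentation fell in 12 of 17 genes, 16 when adjusted over the list alone, with a median of -1.47 (adjusted p = 0.246 with an estimated correlation). The peptide transporter gene Tap1 fell with -2.97 ± 0.51, and the immunoproteasome genes Psmb9 and Psmb8 with -2.84 ± 0.39 and -2.04 ± 0.37. In MHC class II presentation 0 genes rose and 2 of 13 fell (adjusted p = 0.0831).

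Cytokine genes did not fall alike. Tnf (0.34 ± 0.21, limma adjusted p = 0.402), Il6 (-1.19 ± 0.57, adjusted p = 0.233), Il1b (-0.16 ± 0.27, adjusted p = 0.873) and the chemokine gene Ccl5 (-0.20 ± 0.28, adjusted p = 0.818) were not past the threshold. Without LPS array a Tnf rose by 0.65 (adjusted p = 0.0183), and without heme and LPS array c Il6 fell by 1.84 (adjusted p = 0.038). Nos2 fell by 3.75 ± 0.41, Il12b by 3.71 ± 0.85 (by 2.39 without heme and LPS array a) and Il10 by 2.58 ± 0.36. Over the list of pro-inflammatory cytokines and enzymes 6 of 23 genes fell and 1 rose, 6 and 1 when adjusted over the list alone (adjusted p = 0.421 with an estimated correlation); the riser was Il1f9, an interleukin-36 gene, with 3.24 ± 0.49. Of 18 chemokines 7 fell and 2 rose, 8 and 3 when adjusted over the list alone (adjusted p = 0.624 with an estimated correlation), and under quantile normalization the list was not past the threshold (adjusted p = 0.391). The monocyte chemokine genes Ccl7 and Ccl8 fell with -5.57 ± 1.26 and -5.36 ± 1.08. NF-kB pathway genes fell in 9 of 27 cases, 10 when adjusted over the list alone (adjusted p = 0.394 with an estimated correlation), with Dusp2, a MAP kinase phosphatase gene, at -2.84 ± 0.25. Co-stimulation genes fell in 3 of 12 cases, 10 when adjusted over the list alone (adjusted p = 0.232 with an estimated correlation), led by Cd83, a maturation marker gene, with -4.08 ± 0.22; with the replicate letter as a block 6 fell.

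Macrophage genes moved too. In the macrophage identity list 8 of 19 genes fell and 1 rose, 10 and 1 when adjusted over the list alone (adjusted p = 0.369 with an estimated correlation). Fcgr1, a high-affinity IgG receptor gene, fell by 5.38 ± 0.76 and Irf8, a transcription factor gene of the monocyte lineage, by 3.45 ± 0.61, while Cebpa, a myeloid transcription factor gene, rose by 4.45 ± 0.61. Scavenger receptors and efferocytosis had 6 of 22 genes down and 2 up, 8 and 2 when adjusted over the list alone (adjusted p = 0.363 with an estimated correlation); without the LPS-treated arrays lettered a the list was not past the threshold (adjusted p = 0.0561). Clec7a, the beta-glucan receptor gene, was a member that rose, by 3.51 ± 0.69. For Marco, a scavenger receptor gene, the difference was 0.19 ± 0.80 (adjusted p = 1). In the list of anti-inflammatory and alternative activation genes 5 of 23 fell and 1 rose, 5 and 1 when adjusted over the list alone (adjusted p = 0.246 with an estimated correlation), with the transcription factor gene Maf at -2.54 ± 0.21, although its probes differed by 2.88 in their change. Over all genes limma called 1876 higher and 1427 lower. Of the marker lists of other cells, limma called 0 genes of the T and NK cell, erythroid, dendritic cell and mast cell lists, where it called 3303 of all 22485 genes. In the neutrophil list 2 of 15 genes rose (list adjusted p = 0.487). S100a8 rose by 2.05 ± 0.49, lost without heme and LPS array b or LPS array a (adjusted p of up to 0.0549). Elane rose by 1.08 ± 0.23, lost without the LPS-treated arrays lettered a (adjusted p = 0.0754). Of the B cell markers Blnk fell by 2.27 ± 0.41. Of the stromal cell markers Acta2 rose by 1.71 ± 0.39 and Dcn fell by 1.06 ± 0.33, the latter lost without any 1 of the 6 arrays (adjusted p of up to 0.161) or without the arrays lettered a (0.148).

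**Figure D1:**
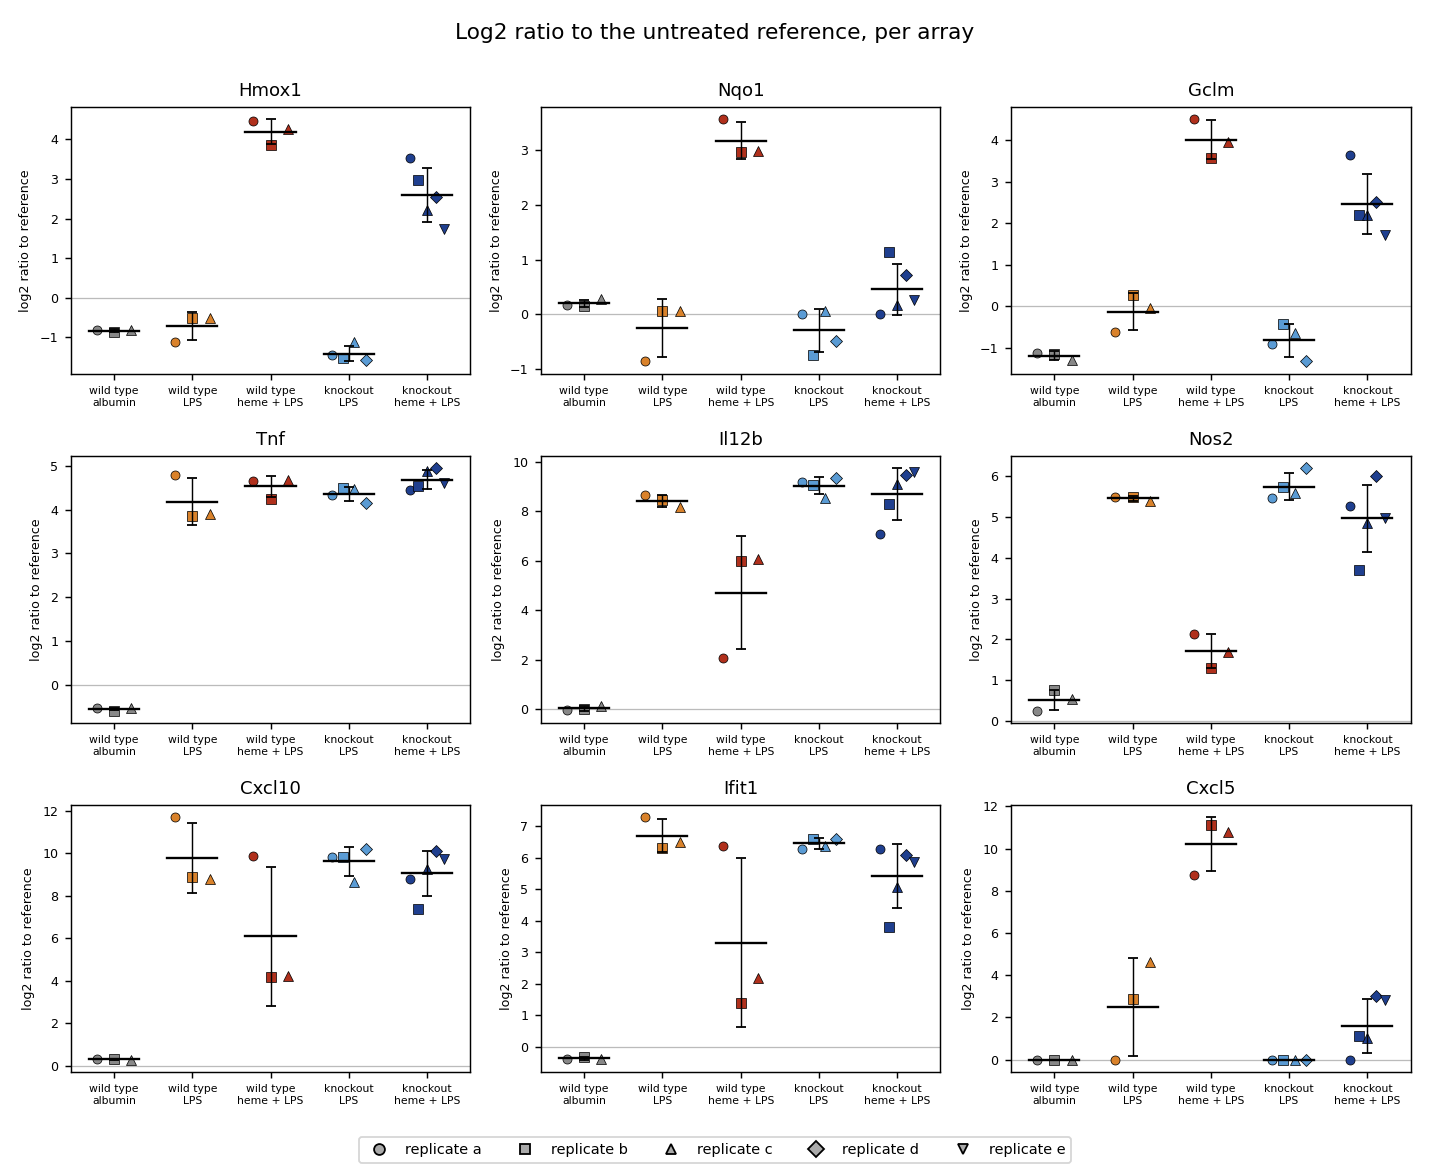
Log2 ratio to the untreated reference (y axis, log2 units) of 9 genes on each array, with the groups along the x axis; marker shapes are the replicate letters, horizontal lines the group means and bars 1 SD. Hmox1 stood at 4.20 ± 0.31 (n = 3) in wild type and 2.60 ± 0.68 (n = 5) in the knockout under heme and LPS, and Nqo1 at 3.18 ± 0.34 and 0.46 ± 0.47.

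The same comparison in the knockout asked which part of the heme response remains without NRF2. Several antioxidant genes still rose. Hmox1 rose by 4.01 ± 0.28, Srxn1 by 3.95 ± 0.31 and Gclm by 3.28 ± 0.33. Osgin1, an oxidative stress induced gene, rose by 3.54 ± 0.33, and Me1, the malic enzyme gene that makes NADPH, by 4.15 ± 0.39 (SE, 5 against 4 arrays). Txnrd1 rose by 1.43 ± 0.28 (limma adjusted p = 0.00644). Nqo1 (0.75 ± 0.26, adjusted p = 0.12) and Slc7a11 (2.58 ± 1.15, adjusted p = 0.259) were not past the threshold. Among the genes that fell were Ddx4, a germ cell helicase gene (-4.39 ± 0.32), the guanylate-binding protein genes Gbp11 (-3.83 ± 0.71) and Gbp9 (-3.12 ± 0.65), Fst (-3.70 ± 0.75) and Fgl2 (-3.31 ± 0.44). Without the LPS-treated arrays lettered a the call of Fst was lost (adjusted p = 0.0571).

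NRF2 targets rose in 17 of 35 cases and fell in 0, 20 and 0 when adjusted over the list alone, with a median of 0.79, and this call held with an estimated correlation (adjusted p = 0.00222). Of 29 heme and iron handling genes 9 rose and 1 fell, 9 and 1 when adjusted over the list alone (adjusted p = 0.246 with an estimated correlation), with Spic up by 2.48 ± 0.50 and Slc48a1 by 2.21 ± 0.16. MHC class I presentation fell in 6 of 17 genes, 13 when adjusted over the list alone, with a median of -0.72 (adjusted p = 0.266 with an estimated correlation); H2-M3 fell by 0.91 ± 0.10. The 6 became 11 with the replicate letter as a block and 2 without the LPS-treated arrays lettered a. In the type I interferon response 1 of 36 genes fell, 0 when adjusted over the list alone by limma, with a median of -1.06 (adjusted p = 0.626 with an estimated correlation). That gene, Ifi204, lost its call without any 1 of 6 arrays, up to an adjusted p = 0.13: heme and LPS b, c or e, or LPS a, b or d. With the replicate letter as a block 7 interferon genes fell, and without the LPS-treated arrays lettered a 3 did. Il10 fell by 1.3 ± 0.29 (adjusted p = 0.0151), though not without the LPS array d (adjusted p = 0.0569) or under quantile normalization (adjusted p = 0.149). Tnf (0.33 ± 0.18), Il6 (-0.37 ± 0.47), Il12b (-0.32 ± 0.70), Nos2 (-0.78 ± 0.34) and Cxcl10 (-0.57 ± 1.02) were not past the threshold, with adjusted p values of 0.393, 0.817, 0.937, 0.238 and 0.906.

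Smaller lists followed. In cholesterol synthesis 3 of 19 genes rose, 4 when adjusted over the list alone, among them Pmvk by 0.80 ± 0.18 (list adjusted p = 0.744 with an estimated correlation). Within letters the median heme effect on this list was -0.58 in a, against 1.535, 0.43 and 0.32 in b, c and d. The integrated stress response had 3 of 27 genes up, 3 when adjusted over the list alone (adjusted p = 0.71 with an estimated correlation), and heat shock and protein folding 2 of 19, 6 when adjusted over the list alone (adjusted p = 0.658 with an estimated correlation), with the co-chaperone gene Bag3 up by 1.31 ± 0.19. Heat shock had 7 genes up with the replicate letter as a block and 7 without the LPS-treated arrays lettered a, and cholesterol synthesis 5 without those arrays. Of 12 co-stimulation genes 2 fell, 3 when adjusted over the list alone (adjusted p = 0.441 with an estimated correlation), with Cd83 at -1.16 ± 0.18. Co-stimulation was not past the threshold under quantile normalization (adjusted p = 0.156) or without the LPS-treated arrays lettered a (adjusted p = 0.0988), nor was the integrated stress response without those arrays (adjusted p = 0.103). Anti-inflammatory and alternative activation genes fell in 4 of 23 cases, 5 when adjusted over the list alone (adjusted p = 0.246 with an estimated correlation). The cell cycle list had a median of -0.58 with 1 of 31 genes down, 0 when adjusted over the list alone by limma (adjusted p = 0.626 with an estimated correlation). H2-Ab1, an MHC class II gene, rose by 0.84 ± 0.21 (limma adjusted p = 0.0287), and its call was lost with the replicate letter as a block (adjusted p = 0.0737), without the LPS-treated arrays lettered a (adjusted p = 0.0721) and without heme and LPS arrays d or e or LPS arrays a, b or d (adjusted p of up to 0.0839). Of markers of other cells limma called 2 genes higher, the neutrophil gene Elane (0.98 ± 0.19) and the stromal gene Acta2 (1.13 ± 0.32). The latter was lost with the replicate letter as a block (adjusted p = 0.101), without the LPS-treated arrays lettered a (0.102) and without any 1 of 8 of the 9 arrays, all but heme and LPS array b (up to 0.166). Over all genes limma called 922 higher and 601 lower, 1523 in total, and 951 without the LPS array a.

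Across all 22485 genes the heme effects of the 2 genotypes had a Pearson correlation of 0.707 and a Spearman correlation of 0.534, and the slope of knockout on wild type was 0.424; genes are not independent replicates. Both genotypes shared 781 genes called higher (76.9 by chance if independent) and 498 called lower (38.1 by chance). Of the genes called in wild type 93.2% of those higher and 96.3% of those lower had the same sign in the knockout, and 4 genes were called in opposite directions. The genotypes share replicate letters whose arrays deviate together, which can add to these values: with the knockout effect taken from letter d alone, which no wild-type array carries, the correlation was 0.508, the slope 0.459 and the covariance 0.261, beside 0.242 with all letters.

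**Figure D2:**
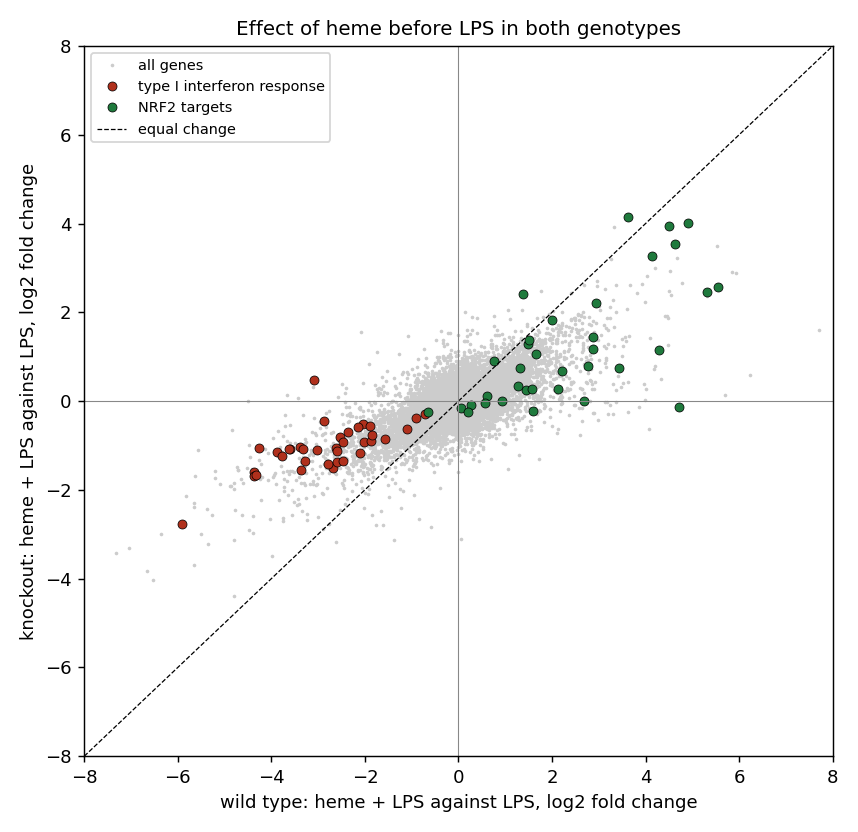
Log2 fold change of heme and LPS against LPS in wild type (x axis) and in the knockout (y axis), 1 point per gene; NRF2 targets and type I interferon response genes are coloured and the dashed line marks equal change. The Pearson correlation over all 22485 genes was 0.707 and the slope 0.424.

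The interaction tested directly whether heme acted differently in the 2 genotypes, and the reference cancels in it. Gsta3, a glutathione transferase gene, rose with heme in wild type by 4.71 ± 0.44, and its effect in the knockout was smaller by 4.84 ± 0.57 (difference -4.84, limma adjusted p = 0.000813). The difference was -2.67 ± 0.42 for Nqo1 (adjusted p = 0.00515) and -2.68 ± 0.40 for Abcc4, an efflux pump gene. Ednrb, an endothelin receptor gene (-4.70 ± 0.60), Rnf183 (-5.66 ± 0.74), Fam13a (-5.56 ± 0.89), Lypd6b (-4.00 ± 0.51) and Slc22a23 (-3.88 ± 0.67) rose with heme in wild type and had a smaller effect in the knockout too. Genes that fell with heme in wild type and had a smaller effect in the knockout stood in the other direction. They were Cd83 (2.92 ± 0.28), Edn1, the vasoconstrictor endothelin (4.50 ± 0.72), Cx3cl1, which encodes fractalkine (3.44 ± 0.51), Themis2 (3.47 ± 0.45), Dusp2 (2.57 ± 0.32) and Nos2 (2.96 ± 0.53, adjusted p = 0.0144). Nos2 was not past the threshold without the LPS-treated arrays lettered a (adjusted p = 0.0851). For Cxcl5 the difference was -6.12 ± 1.28 (adjusted p = 0.0375), and the call was lost without any 1 of 9 arrays, with an adjusted p of up to 0.105: wild-type heme arrays b or c, knockout heme array c, wild-type LPS arrays a or b, or any knockout LPS array. Hmox1 (-0.90 ± 0.44, adjusted p = 0.674), Srxn1 (-0.56 ± 0.49, adjusted p = 0.935) and Gclm (-0.87 ± 0.52, adjusted p = 0.818) were not past the threshold. Nor were Il12b (3.38, limma adjusted p = 0.26), Slc7a11 (-2.96, adjusted p = 0.823) and Cxcl10 (3.14, adjusted p = 0.708). Without wild-type heme array a Il12b stood at 2.07, while Cxcl10 stood at 5.03 and was past the threshold (limma adjusted p = 0.0336). Slc7a11 stood at -1.60 without wild-type LPS array a.

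NRF2 targets had 9 of 35 genes with a smaller heme effect in the knockout and 0 with a larger one, 18 and 0 when adjusted over the list alone, with a median difference of -0.90, and the call held with an estimated correlation (adjusted p = 0.00128). The type I interferon response had a median difference of 1.62, but limma called 0 of its 36 genes, and 0 when adjusted over the list alone. Over all 22485 genes it called 213, so few calls would be seen among 36 genes in any case. The list had a camera adjusted p = 0.413 with an estimated correlation. Within letters shared by the groups the median heme effect on the list was -1.47, -3.62 and -2.75 in wild type a, b and c, and -0.55, -2.26, -0.91 and -0.67 in knockout a, b, c and d. For Ifnb1 the value was 3.55 ± 0.96 (adjusted p = 0.127), which is not past the threshold (4.33 without wild-type LPS array a, adjusted p = 0.0455). NF-kB pathway genes had 2 of 27 higher, 2 when adjusted over the list alone, and a median of 0.76. Cytokines had 1 higher and 1 lower of 23, 5 and 1 when adjusted over the list alone, and a median of 0.75. Both lists had an adjusted p = 0.325 with an estimated correlation. Chemokines (1 higher and 1 lower of 18, 2 and 1 when adjusted over the list alone) had an adjusted p = 0.388 with an estimated correlation, MHC class I presentation (0 of 17, 4 higher when adjusted over the list alone) an adjusted p = 0.421 with an estimated correlation, and co-stimulation (1 of 12, 2 when adjusted over the list alone) an adjusted p = 0.246 with an estimated correlation. Without the LPS-treated arrays lettered a chemokines had 3 and interferon genes 2 higher. Macrophage identity (0 of 19, 1 when adjusted over the list alone) had a median of 0.62 and an adjusted p = 0.369 with an estimated correlation. In total limma called 54 genes with a higher and 159 with a lower heme effect in the knockout. The total of 213 became 135 without wild-type LPS array b, 140 without wild-type heme array c and 323 without knockout heme array b.

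LPS raised 655 genes at least 4-fold in wild type, and these were followed under heme; 12 of them were listed at exactly 0 on every albumin array. In wild type 598 (91.3%) were lower under heme and LPS than under LPS, 385 (58.8%) of them past the threshold, and 7 were past it in the other direction; the median change was -1.63. In the knockout 556 (84.9%) were lower, 136 (20.8%) past the threshold, with 6 past it upward and a median of -0.71. Genes picked for a high value under LPS in wild type lie lower in any comparison with that group. Simulated unchanged groups had 57.3% lower in wild type (62.4% at most in 20 simulations) and 49.7% in the knockout (54.6% at most). The simulations drew genes and arrays independently. Real arrays of a letter deviate together and real genes can move together, so the range of such shares by chance can be wider than these maxima. Both genotypes called 124 of the genes lower. For 88.5% of the 655 genes the interaction was above 0 (55.8% in the simulations, 59% at most), counting also genes that did not fall. The median difference was 0.89, and the interaction was past the threshold for 26 genes higher and 1 lower. The knockout share past the threshold was 11.2% without knockout LPS array a and 11.9% without knockout LPS array d, 13.7% after quantile normalization and 31.2% with the replicate letter as a block. In letter d alone 79.4% of the genes were lower in the knockout, with a median of -0.58.

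**Figure D3:**
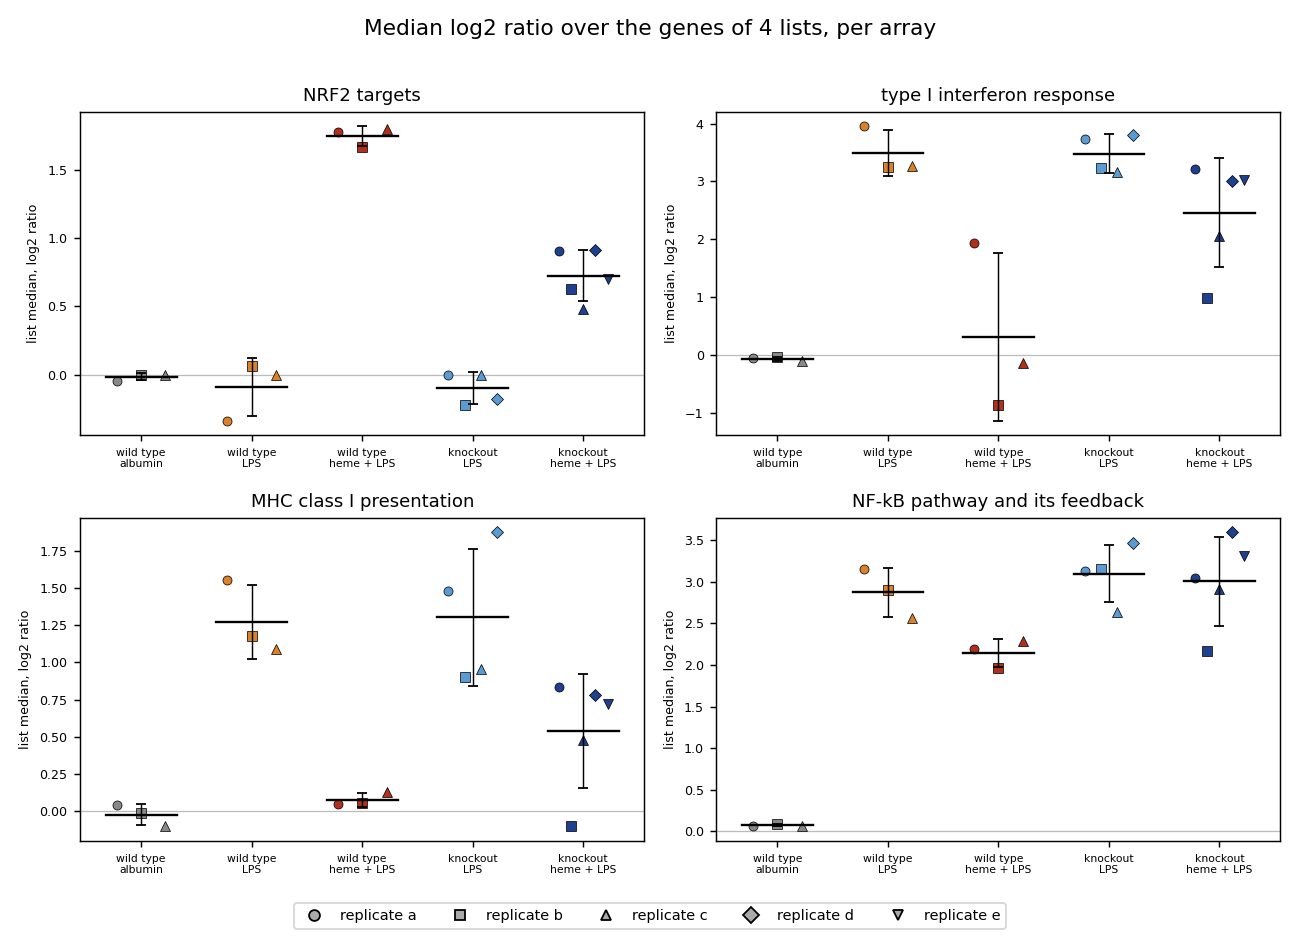
Median log2 ratio to the reference (y axis, log2 units) over the genes of 4 lists on each array, with the groups along the x axis; marker shapes are the replicate letters, horizontal lines the group means and bars 1 SD. The interferon median was 1.93, -0.86 and -0.13 on the wild-type heme and LPS arrays a, b and c.

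Knockout and wild type were compared under LPS alone to see whether the loss of Nrf2 changed the response before heme was added. The inflammatory genes named here were not past the threshold. The difference was 0.18 ± 0.20 for Tnf, 0.48 ± 0.54 for Il6, 0.61 ± 0.79 for Il12b, 0.29 ± 0.39 for Nos2 and -0.16 ± 1.16 for Cxcl10 (SE, 4 against 3 arrays), all with a limma adjusted p of 1. Among NRF2 targets the values were -1.59 ± 0.35 for Srxn1, -0.70 ± 0.32 for Hmox1 and -0.05 ± 0.30 for Nqo1, also with an adjusted p of 1. The 1 gene past the threshold was Prm1, a sperm protamine gene, which was lower in the knockout by 2.56 ± 0.25 (difference -2.56, adjusted p = 0.00116); with the replicate letter as a block its adjusted p was 0.106. Limma called 0 genes higher, and 557 of 22485 genes had an unadjusted p under 0.05, where 1124 would be expected by chance. Arrays of the same letter deviated together in these groups, which the reported fit leaves out and which can raise its p values. A count under that of chance is thus no evidence that the genotypes are alike. With the replicate letter as a block limma called 0 genes, with 920 at an unadjusted p under 0.05. The count of 1 became 3 without wild-type LPS array a and 2 without wild-type LPS array b.

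By list, 4 passed the threshold in this comparison with no single gene past it. Cholesterol synthesis had a median of -0.54 (adjusted p = 0.441 with an estimated correlation), with Cyp51, a sterol demethylase gene, at -0.94 ± 0.34. Glycolysis and hypoxia response had a median of -0.25 (adjusted p = 0.0822 with an estimated correlation) and was not past the threshold without the LPS-treated arrays lettered a (adjusted p = 0.0575). Oxidative phosphorylation had a median of -0.07 (adjusted p = 0.626 with an estimated correlation); its adjusted p was 0.0681 with the replicate letter as a block, 0.0651 under quantile normalization and 0.354 without the LPS-treated arrays lettered a. Stromal cell markers, which include Sparc (1.67 ± 0.66, and 0.73 without wild-type LPS array b) and Col1a1 (1.63 ± 0.96, and -0.14 without that array), had a median of 0.44 (adjusted p = 0.421 with an estimated correlation), and their adjusted p was 0.213 with the replicate letter as a block. Col1a1 stood at 2.59 without wild-type LPS array a. Adjusted over the list alone, 0 genes of these 4 lists were called by limma. NRF2 targets had a median of -0.02 with 0 called by limma and 1 lower when adjusted over the list alone (list adjusted p = 0.14).

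Under heme and LPS knockout and wild type were set side by side as well. NRF2 targets stood lower in the knockout: Gsta3 by -5.04 ± 0.39, Gclc by -3.24 ± 0.43, Abcc4 by -2.85 ± 0.28, Nqo1 by -2.72 ± 0.29, Srxn1 by -2.15 ± 0.34 and Hmox1 by -1.60 ± 0.31 (SE, 5 against 3 arrays). Cxcl5 was lower by 8.61 ± 0.89 (difference -8.61). Also lower were Ppbp, a platelet and neutrophil chemokine gene (-4.25 ± 0.30), Il1f9 (-4.14 ± 0.44), Fam13a (-4.87 ± 0.61), Ednrb (-4.12 ± 0.42) and Lypd6b (-4.00 ± 0.35). Higher in the knockout were Edn1 (4.71 ± 0.49), the endothelial lipase gene Lipg (4.73 ± 0.58), Ifnb1 (4.49 ± 0.66), Il12b (3.99 ± 0.76), Cx3cl1 (4.03 ± 0.35), Nos2 (3.26 ± 0.37) and Dll1, a Notch ligand gene (3.73 ± 0.63). Il12b was not past the threshold under quantile normalization (adjusted p = 0.0583). Tnf (0.16 ± 0.19, adjusted p = 0.777) and Il6 (1.3 ± 0.51, adjusted p = 0.206) were not past the threshold. Without wild-type array c Il6 was past it (1.95, limma adjusted p = 0.0443). The difference of Nfe2l2 was -0.64 ± 0.17 (adjusted p = 0.0456), which was lost with the replicate letter as a block (adjusted p = 0.0739) and without any 1 of 7 of the 8 arrays (all but wild-type array a, adjusted p of up to 0.219).

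Of 35 NRF2 targets 21 were lower in the knockout and 0 higher, 24 and 1 when adjusted over the list alone, with a median of -0.98, and the call held with an estimated correlation (adjusted p = 0.00128). Nfe2l2, the gene knocked out, is 1 of the 21. Glycolysis and hypoxia response had 9 of 27 genes lower, 16 lower and 1 higher when adjusted over the list alone, and held as well (adjusted p = 0.0178 with an estimated correlation, and 0.0327 without Pigq and Eno1b, which were found under synonyms of Gpi1 and Eno1); Bnip3, a mitophagy receptor gene, differed by -1.51 ± 0.24 and Pgk1, a glycolytic enzyme gene, by -0.89 ± 0.16. The type I interferon response had 6 of 36 genes higher, 26 when adjusted over the list alone, with a median of 1.52 (adjusted p = 0.393 with an estimated correlation), and 25 were higher without the LPS-treated arrays lettered a. On the wild-type side the list median was 1.93 on array a, -0.86 on array b and -0.13 on array c, and on the knockout side it lay between 0.98 and 3.22. NF-kB pathway genes were higher in 5 of 27 cases, 12 when adjusted over the list alone (adjusted p = 0.266 with an estimated correlation), with Tnfaip2 at 1.52 ± 0.13 and Tlr2 at 1.42 ± 0.24. Cytokines had 6 of 23 higher and 1 lower, the same numbers when adjusted over the list alone (adjusted p = 0.246 with an estimated correlation). Chemokines had 2 of 18 higher and 1 lower, 9 and 1 when adjusted over the list alone (adjusted p = 0.271 with an estimated correlation), with Cxcl9 at 3.37 ± 0.55, although its probes differed by 2.70 in their heme effect in wild type. Without the LPS-treated arrays lettered a 7 chemokines and 8 NF-kB pathway genes were higher. MHC class I presentation (3 of 17 higher, 6 when adjusted over the list alone) had an adjusted p = 0.45 with an estimated correlation, co-stimulation (3 of 12 higher, 4 higher and 1 lower when adjusted over the list alone) an adjusted p = 0.246 with an estimated correlation, and macrophage identity (2 of 19 higher and 1 lower, 6 and 1 when adjusted over the list alone) an adjusted p = 0.393 with an estimated correlation. Of 29 heme and iron handling genes 6 were lower (median 0.09, mean -0.18, list adjusted p = 0.548), among them Fech, the enzyme that makes heme, with -1.32 ± 0.16. Of markers of other cells the neutrophil gene S100a8 was lower (-1.95 ± 0.44). This was lost with the replicate letter as a block (adjusted p = 0.0592) and without wild-type array b or c (adjusted p of up to 0.0971). The B cell gene Blnk was higher (1.44 ± 0.37). Its call was lost without any 1 of 7 of the 8 arrays (all but knockout array a, adjusted p of up to 0.151). Over all genes limma called 479 higher and 710 lower. If each genotype was set against a reference of its own, the values of these comparisons of genotypes are differences of responses.

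Heme and LPS against albumin in wild type showed what the joint treatment did compared with unstimulated cells, with 4 h of albumin by the labels against 4 h of heme-albumin and 4 h of LPS. Chemokine genes that attract neutrophils were among those that rose. Cxcl2 rose by 10.04 ± 0.57 and Cxcl1 by 7.65 ± 0.53 (SE, n = 3 per group), and Cxcl5 stood at 10.20 ± 1.28 (SD) with all 3 albumin arrays listed at exactly 0. Slc7a11 rose by 9.46 ± 1.40 and Ptgs2 by 9.30 ± 0.52, Il1b by 7.11 ± 0.27, Tnf by 5.08 ± 0.21, Gclm by 5.20 ± 0.40 and Hmox1 by 5.03 ± 0.34. The cholesterol exporter gene Abcg1 fell by 4.71 ± 0.42, Lyl1 by 5.07 ± 0.31, the receptor gene Gpr34 by 4.81 ± 0.56 and Rasgrp3, a Ras activator gene, by 4.62 ± 0.68. Of markers of other cells the neutrophil genes S100a8 (3.40 ± 0.49) and Ngp (1.60 ± 0.35) and the NK cell gene Ncr1 (1.38 ± 0.33) rose. The B cell gene Blnk (-2.82 ± 0.41) and the dendritic cell gene Itgae (-1.34 ± 0.33) fell. Cd79b of B cells fell by 1.49 ± 0.39, lost without heme and LPS array c (adjusted p = 0.0507). Nkg7 of NK cells rose by 0.26 ± 0.08, lost without any 1 of 4 arrays (albumin a or c, heme and LPS b or c, adjusted p of up to 0.108). Acta2 of stromal cells rose by 1.16 ± 0.39, lost without any 1 of 5 of the 6 arrays (all but heme and LPS array c, up to 0.163) and without the LPS-treated arrays lettered a (0.138). Over all genes limma called 2903 higher and 3239 lower.

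Of 35 NRF2 targets 29 rose and 1 fell, 31 and 1 when adjusted over the list alone, and the call held with an estimated correlation (adjusted p = 0.00128). Pro-inflammatory cytokines rose in 12 of 23 cases, 12 when adjusted over the list alone (adjusted p = 0.102 with an estimated correlation), chemokines in 9 of 18, 10 when adjusted over the list alone (adjusted p = 0.246 with an estimated correlation), and NF-kB pathway genes in 20 of 27, 24 when adjusted over the list alone (adjusted p = 0.19 with an estimated correlation). The type I interferon response, with 34 of 36 genes up under LPS alone, had 8 up, 8 when adjusted over the list alone, and a median of 0.68 (adjusted p = 0.884 with an estimated correlation). Without the LPS-treated arrays lettered a 4 of its genes rose and 4 fell, the median was -0.05 and the list was not past the threshold (adjusted p = 0.987). Cell cycle genes fell in 21 of 31 cases, 24 when adjusted over the list alone, with a median of -1.81 (adjusted p = 0.369 with an estimated correlation); Ccna2, which encodes cyclin A, fell by 3.49 ± 0.84 and Cdt1 by 3.30 ± 0.47. Of 27 integrated stress response genes 9 rose, 10 when adjusted over the list alone (adjusted p = 0.49 with an estimated correlation), and of 19 heat shock and protein folding genes 10 rose, 12 when adjusted over the list alone (adjusted p = 0.501 with an estimated correlation), with the heat shock protein gene Hspa1a up by 4.35 ± 0.59. Heme and iron handling genes rose in 14 of 29 cases and fell in 3, 14 and 6 when adjusted over the list alone (adjusted p = 0.393 with an estimated correlation); with the replicate letter as a block 7 fell. Of the chemokines 0 fell, and 3 did without the LPS-treated arrays lettered a.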

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

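Chosen after the result was seen were the tests of the interferon genes on wild-type heme array a, of a reference of each genotype's own and of wild-type cells in the knockout cultures. Those of the number of arrays and of the splits were set before. That of the arrays lettered a in the knockout was set before its own result, but on a fit chosen after the data were seen.

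Heme acted differently in the 2 genotypes by the interaction test for 213 genes. By list the median difference was -0.90 for NRF2 targets, 0.75 for pro-inflammatory cytokines and enzymes, 0.68 for chemokines, 1.62 for the type I interferon response, 0.76 for the NF-kB pathway, 0.43 for MHC class II presentation, 0.57 for MHC class I presentation and 0.70 for co-stimulation. It was 0.31 for scavenger receptors and efferocytosis, 0.55 for cholesterol synthesis, -0.29 for glycolysis and hypoxia response, 0.47 for the cell cycle and 0.62 for macrophage identity. Of these 13 lists, NRF2 targets alone passed with an estimated correlation (adjusted p = 0.00128). Adjusted p values with an estimated correlation were 0.451 for MHC class II presentation, 0.441 for scavenger receptors, 0.627 for cholesterol synthesis, 0.167 for glycolysis and 0.73 for the cell cycle. Among single genes named in advance the difference was -2.67 for Nqo1 and 2.96 for Nos2.

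Of 100 reassignments of the genotypes within each treatment, 4 gave as many genes as the real 213, the real one included, and the highest other gave 519. The share is under 5%, but splits that call more genes than the real one point to a structure of the samples. Heme and LPS against LPS in the knockout called 1523 genes and 1 of 100 splits gave as many, the real one, with 320 in the highest other. Knockout against wild type under heme and LPS called 1189 genes and 1 of 56 splits gave as many, the real one, with 628 in the highest other. Over all splits both shares are under 5%, but the splits that part as many pairs of letters were 13 and 8, too few for a share under 5%, and the highest others among them gave 0 and 1. Under LPS alone chance was not excluded for the 1 gene called: 6 of 35 splits gave as many, and 2 of the 8 that part as many pairs. The highest split there called 125 genes and parts 0 pairs, so it sets letters against each other, which is a structure of the samples. Each of the 3 wild-type comparisons has 10 splits, too few for a share under 5%, and 1 of the 10, the real one, gave as many genes. The real values and highest others were 6433 and 3 for LPS against albumin, 3303 and 5 for heme and LPS against LPS, and 6142 and 12 for heme and LPS against albumin.

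Interferon genes stood higher on wild-type heme and LPS array a (list median 1.93) than on arrays b (-0.86) and c (-0.13). A shift common to the LPS and heme arrays lettered a is argued against as the whole cause, since the heme effect within letter a was -1.465, against -3.62 and -2.75 within b and c. The knockout letters had the same order, with list medians of 3.22, 0.98 and 2.05 on heme arrays a, b and c and effects of -0.55, -2.26 and -0.91 within them, so an effect of the letter on the heme arrays of both genotypes, such as of the mice or cultures, stays open. Setting weak ratios to exactly 0 is argued against too for genes with all probes at 0: the 36 genes had no such case on the wild-type LPS-treated arrays, and over them the gap was 2.38. Single probes at exactly 0 within a gene were not looked at. Much less heme in that culture is argued against by the NRF2 target median, 1.783 on array a against 1.671 and 1.801, a difference of 0.112 from the lower, though that response may be saturated.

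Few genes differed between knockout and wild type under LPS. Whether too few arrays hid large differences is not settled. A share of 0.88 of simulated 4-fold changes was called at these group sizes, but with 200 genes changed at once and arrays drawn independently. Where few genes change the adjusted threshold is harder to pass, and the real arrays of a letter deviate together, so this share does not carry over. An untreated reference of each genotype's own, although the design text speaks of a common one, could hide differences present before treatment, and it would leave Nfe2l2 at or above 0 in the knockout. Of the 9 knockout arrays 0 had a ratio below 0, but all 9 were at exactly 0, as were 2 of 3 albumin arrays, so this cannot be told apart from a common reference. A response to LPS that depends little on Nrf2 also stays open.

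NRF2 targets rose with heme in the knockout. The knockout arrays lettered a are argued against as the cause, since 18 targets rose without the LPS-treated arrays of that letter. Wild-type cells in the knockout cultures would give 1 ratio of knockout to wild-type induction on the linear scale if levels under LPS were alike, and 115 of 435 pairs of targets had ratios with intervals apart, with a median ratio of 0.194 and a range of -0.0719 to 2.69. Taken on the levels relative to the common reference of the design text, which needs no alike levels, 200 of 435 pairs were apart, with Gsta3 at 0.0137 at most and Ftl1 at 0.658 at least, so such cells are argued against as the whole cause. The 30 targets paired here include Nfe2l2 itself, which was listed at exactly 0 in the knockout. A route to these genes that does not need Nrf2 is the biological explanation that the design offers; it was not tested.

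In 95 groups tested for a single array far from the others 8 were found. For values without ties chance would give about 1 in 20 groups, 4.75 in all. That rate does not hold here, since many values are exactly 0. Where all others are at 0, any 1 array off 0 is found, as in those cases below with the others at 0. Ciita, the master regulator gene of MHC class II, stood at 0.589 on knockout LPS array b with the others at 0, and at 0.634 on knockout heme array c with the others between -0.0384 and 0.0697. The anti-inflammatory list median stood at -0.15 on knockout heme array b with the others at 0. Neutrophil markers stood at 0.348 on knockout LPS array d with the others between 0 and 0.0408. B cell markers stood at -0.376 on knockout LPS array d and at -0.437 on knockout heme array b, with the others at 0. T and NK cell markers stood at 0.67 on knockout heme array e with the others between 0 and 0.0759. Mast cell and basophil markers stood at 0.169 on knockout heme array d with the others between 0 and 0.0343.

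Features without a gene symbol, which no comparison used, also passed the threshold. There were 1542 for LPS against albumin, 452 for heme and LPS against LPS in wild type and 136 in the knockout, 13 for the interaction, 1 and 159 for knockout against wild type under LPS and under heme and LPS, and 1356 for heme and LPS against albumin.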

How the results depend on the processing

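Chosen after the data were seen were the fits without the LPS-treated arrays lettered a, with exact 0 as missing and centred on the nonzero median, the block for LPS-induced genes, leaving out arrays for named genes and the correlation, and the glycolysis list without Pigq and Eno1b, under which all 78 list calls held. Array medians were already 0, so centring on them changes nothing. Robust eBayes, the most variable probe, each probe on its own, only the genes with variance above the median, leaving out probes at exactly 0 and exact 0 as missing (13920 genes tested) kept each count of called genes within 1.5 times. No called gene or list named here turned its direction under any alternative run for it, except that the interferon median for heme and LPS against albumin was -0.05 without the arrays lettered a. What sets a ratio to exactly 0 is not given in the sources used here.

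A 2-fold minimum gave 3747 genes for LPS against albumin, 1942 for heme and LPS against LPS in wild type and 572 in the knockout, 634 for knockout against wild type under heme and LPS and 3497 for heme and LPS against albumin, by construction. Array weights gave 5340 genes for heme and LPS against LPS in wild type, 879 for the interaction and 2124 for knockout against wild type under heme and LPS; the cause was not tested. Fits of the compared arrays only gave 1545 genes for heme in wild type, 752 in the knockout and 116 for the interaction. They gave 0 for knockout against wild type under LPS (699 at an unadjusted p under 0.05 in limma) and 317 under heme and LPS. Counts of the 2 comparisons with albumin stayed within 1.5 times. Fewer arrays estimate the spread in these fits, but the one for the interaction left out the albumin arrays alone. The reported counts of the other 5 comparisons thus depend on 1 spread shared by all groups, and the cause was not tested. The replicate block ended no call of a gene or list in the text other than those named with it. It gave 0 genes for knockout against wild type under LPS (920 at an unadjusted p under 0.05 in limma), and 31.2% of LPS-induced genes past the threshold lower in the knockout, where quantile normalization gave 13.7%. Knockout against wild type under LPS had 6 genes without the arrays lettered a, among them Prm1 (-2.15), Cd80 (0.84) and Afap1l2 (3.58), picked after their values were seen. Of the genes called, 5479 for LPS against albumin, 2429 and 1217 for heme in wild type and knockout, 146 for the interaction, 912 for knockout against wild type under heme and LPS and 5184 for heme and LPS against albumin were also called without those arrays. The correlation of the heme effects was 0.85 over genes called in either genotype, by the choice of genes.

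Leaving out 1 array gave 5425 to 5557 genes for LPS against albumin, 2618 to 2891 and 951 to 1637 for heme in wild type and knockout, 135 to 323 for the interaction, 1 to 3 and 798 to 1560 for knockout against wild type under LPS and under heme and LPS, and 5076 to 5506 for heme and LPS against albumin. The correlation was 0.642 to 0.735. Of LPS-induced genes 90.2% to 93.2% were lower in wild type (47% to 60.9% past the threshold) and 78.3% to 87.9% in the knockout (11.2% to 24% past it); the lowest were without knockout LPS array a (11.2%) and d (11.9%).

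With an estimated correlation 0 comparisons passed for heme and iron handling, chemokines, type I interferon response, NF-kB pathway, LPS receptor and signalling, MHC class II and class I presentation, co-stimulation, anti-inflammatory and alternative activation, scavenger receptors, integrated stress response, heat shock, cholesterol synthesis, lysosome, oxidative phosphorylation, cell cycle, macrophage identity and stromal markers, and 1 each for the cytokines and for glycolysis. Lysosome had 0 under quantile normalization and with the block, and stromal markers 0 with the block. Without the arrays lettered a MHC class II and scavenger receptors had 0, the integrated stress response, oxidative phosphorylation, p53 targets and neutrophil markers 1, and lysosome and stromal markers 2. The cause was not tested. Counts of called lists that moved by more than 1.5 times with the block or without those arrays, other than those given with the lists, stayed at 2 genes or fewer. The list calls were 78 as reported, and the same 73 held under quantile normalization, 74 with the block, 64 without the arrays lettered a and 77 on the nonzero median. Of 143 calls of genes named in advance or for the size of their change, 140 held under quantile normalization, 137 with the block, 134 without the arrays lettered a and 124 without any 1 array.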

Other observations

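The test of the neutrophil chemokines was chosen after the result was seen, and that of the fall of interferon genes against their rise under LPS was set before.

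Genes of metabolism also moved. The 27 genes of the next list include Pigq, a gene of GPI anchor synthesis, and Eno1b, found under synonyms of Gpi1 and Eno1, which have no probe under their names. Without them 1 gene of 25 fell in place of 2 under LPS and under heme and LPS against albumin, and no list call was lost. In glycolysis and hypoxia response, the program of sugar breakdown and low oxygen, 7 of 27 genes rose and 2 fell under LPS, 7 and 2 when adjusted over the list alone (adjusted p = 0.369 with an estimated correlation), led by Acod1, which makes itaconate, with 6.28 ± 0.58 (SE, n = 3 per group). Without the LPS-treated arrays lettered a the list had 4 genes down under LPS and was not past the threshold (adjusted p = 0.0547). Heme in wild type raised 11 and lowered 2 of its genes, 11 and 4 when adjusted over the list alone (adjusted p = 0.369 with an estimated correlation), with the glucose transporter gene Slc2a1 up by 1.70 ± 0.26; with the replicate block 4 fell. Against albumin heme and LPS raised 16 and lowered 2, 17 and 3 when adjusted over the list alone (adjusted p = 0.102 with an estimated correlation). In the knockout heme raised 3 and lowered 2, among the risers P4ha2, a collagen hydroxylase gene, by 1.08 ± 0.21 (list adjusted p = 0.977). Oxidative phosphorylation fell in 9 of 27 genes and rose in 1 under heme and LPS against albumin, 10 and 1 when adjusted over the list alone (adjusted p = 0.627 with an estimated correlation). In the knockout the heme effect on that list had a median of -0.10 (camera adjusted p = 0.626 with an estimated correlation, and 0.146 with the preset correlation without the arrays lettered a). Limma called 0 genes of the list, also when adjusted over the list alone, where it called 1523 of all 22485 genes.

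Lipid genes included Abcg1, the cholesterol exporter, which fell with heme by 4.48 ± 0.42 in wild type and by 2.90 ± 0.34 in the knockout (limma adjusted p = 0.000178), with an interaction not past the threshold (adjusted p = 0.309). The LXR list, named for a sterol sensor, had 4 of 19 genes down and 2 up with heme in wild type and no list call in any comparison (adjusted p = 0.599 in this one). Lysosome genes fell in 3 of 25 cases with heme in the knockout, 3 lower and 1 higher when adjusted over the list alone (adjusted p = 0.71 with an estimated correlation, and with the preset correlation 0.055 under quantile normalization and 0.0522 with the replicate block), and 1 fell with the block or without the arrays lettered a. Genes of the LPS receptor and its signalling rose in 10 of 20 cases and fell in 2 under LPS, 10 and 4 when adjusted over the list alone (adjusted p = 0.136 with an estimated correlation), with the co-receptor gene Cd14 at 2.50 ± 0.31 and the kinase regulator gene Tab1 at -2.42 ± 0.14. Under heme and LPS against albumin 11 of them rose and 2 fell, 12 and 2 when adjusted over the list alone (adjusted p = 0.0804 with an estimated correlation). Among p53 targets and cell death genes 3 of 23 rose and 5 fell with heme in wild type (list adjusted p = 0.073), with the caspase gene Casp8 at -1.85 ± 0.25 and the pore-forming gasdermin gene Gsdmd at -1.47 ± 0.26. Cell cycle genes fell in 3 of 31 cases with heme in wild type, 3 when adjusted over the list alone (adjusted p = 0.49 with an estimated correlation), among them Tyms, which makes thymidylate (-2.13 ± 0.30); with the replicate block 6 fell.

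Under heme and LPS the knockout had 5 of 22 scavenger receptor genes higher and 2 lower than wild type, 7 and 2 when adjusted over the list alone (adjusted p = 0.363 with an estimated correlation). It had 1 of 27 integrated stress response genes higher and 1 lower, 1 and 2 when adjusted over the list alone (adjusted p = 0.724 with an estimated correlation), 2 of 19 heat shock genes lower, 3 when adjusted over the list alone (adjusted p = 0.71 with an estimated correlation), and 1 of 31 cell cycle genes higher, 1 when adjusted over the list alone (adjusted p = 0.74 with an estimated correlation). The first 3 of these were not past the threshold without the arrays lettered a (adjusted p = 0.111, 0.498 and 0.354), where 3 cell cycle genes were higher. In the interaction the scavenger list was lost under quantile normalization (adjusted p = 0.053), with the replicate block (0.0512) and without those arrays (0.215), and MHC class II presentation without those arrays (0.0875). Of the markers of other cells no list other than the stromal one was called in any comparison. For heme in wild type the adjusted p was 0.487 for neutrophil, 0.804 for B cell, 0.978 for T and NK cell, 0.977 for erythroid, 0.723 for dendritic cell and 0.563 for mast cell and basophil markers, and 0.977 for stromal cell markers.

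Cxcl1, Cxcl2, Cxcl3 and Cxcl5, chemokines with the ELR motif that attract neutrophils, had a mean heme effect of 3.77 in wild type, against -2.45 for the 14 other chemokines of the list (one-sided exact permutation p = 0.000327 over 3060 arrangements, the smallest they can give). The 4 genes were picked after their change was seen, so this p restates the pick and is no test of whether they respond apart, and genes are not independent replicates. Cxcl1 and Cxcl3 were not past the threshold in wild type (limma adjusted p = 0.0914 and 0.242). In the knockout the means were 1.6 and -0.551, with letters shared between the genotypes, and of the 18 chemokines Cxcl2 alone rose (1.90 ± 0.47, adjusted p = 0.0235). That call was lost with the replicate block (adjusted p = 0.0677), without the arrays lettered a (0.0541) and without any 1 of 6 of the 9 arrays (up to 0.088).

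Interferon genes that LPS raised further in wild type could be those that fell further with heme in the knockout. The 2 comparisons share no array, but their LPS arrays share letters that deviate together, which can push this correlation below 0. Spearman's rho across the 36 genes was -0.252 with a jackknife SE of 0.179, and the bound of -0.3 set in advance lies within that spread, so the data do not decide. With the knockout effect from letter d alone, which no wild-type array carries, rho was -0.0466.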
